A study of Drosophila melanogaster with 3 samples.

How the data were processed

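The samples were 3 biological replicates of 1 group, taken from the labels: anti-GFP chromatin immunoprecipitation followed by sequencing from whole embryos (0 to 24 h) of a line expressing tagged HmgD. Per the labels' protocols, chromatin was sheared by sonication to fragments of 200 to 800 bp. Each replicate had a list of candidate peaks in narrowPeak format, meant as input to the IDR step and therefore holding background entries too. The series as a whole had a candidate list made from the 3 alignments pooled, and a list of peaks passing the IDR threshold, each on the dm6 and dm3 builds, per the file descriptions deposited with them. The same descriptions say that the candidate lists were derived with a control file. The control data were not used here. The aligner, the peak caller, the annotation and the IDR threshold are not given in the sources used here.

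The signal of each peak is the authors' own value, deposited in the signal column of the narrowPeak files, on a scale that differs between lists, and was used here only to rank, filter or describe peaks within a list. The deposited lists also carry a −log10 q per peak, made by the authors, which was read and is not used for any comparison. Peak widths were nearly uniform within a list (376 bp in replicate 1, 404 in replicate 2, 420 in replicate 3 and 404 in the pooled list), and 243 of 2964 IDR peaks were narrower than 404 bp. The files hold no read counts, so the depth per replicate is unknown, and no interval that needs it is given. Intervals on shares cover the sampling of peaks or genes only. The lists of replicates 2 and 3 and the pooled list each held 30000 entries, so the length of a list was not read as a measure of binding.

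The lists on dm6 were read with 1-based coordinates and set against the Release 6 sequence and the Ensembl 115 gene annotation. Peak ends lay within the reference lengths of the arms. No candidate of the dm6 lists lay on Y or on unplaced sequences, so Y was not tested. dm3 coordinates were not converted and served only for alternatives that need no annotation. Summits in different lists were matched when mutually nearest and within 200 bp. Overlap of the strongest candidates was set against 200 circular shifts along each arm, and location against 1000. A promoter was defined as 500 bp either side of any annotated TSS, and other summits were placed in 5' untranslated, coding, 3' untranslated, noncoding exon, intron or intergenic sequence. Transposable element annotations were left out.

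Chromosome arms, gene lists and words were tested with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment within each family at 0.05. With sequence length as background, arms were instead tested with a binomial test, and the value is a ratio of shares. Gene lists compared members with all other genes on the arms. Words were searched within 100 bp of the summit on both strands. GC content was compared by a permutation test of medians with 100000 permutations. Odds ratio intervals are Woolf's at 95%. Peaks and neighbouring genes are not independent replicates, so these p-values describe the lists, and the spread between replicates was computed from the 2964 strongest candidates of each replicate (n = 3). The 28 gene lists, 11 words, the tests of the Results, their alternatives and the rule for named genes were fixed before the data were examined. The GC comparison outside promoters and most tests of the additional observations were chosen later, as stated there. In the annotation, 22 of 23 Polycomb and trithorax symbols, all 21 architectural and insulator symbols and all 26 replication and cell cycle symbols were matched.

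The genes named are those nearest to the 10 IDR peaks of highest signal; for each list with a higher share, the 3 members with the strongest promoter peak; for each with a lower share, up to 2 members with one; for each list that did not pass, the member with the strongest promoter peak; and HmgD, HmgZ and Dsp1 in any case. Alternatives covered the match distance, reciprocal overlap of 50%, promoter windows of 250 and 1000 bp, other backgrounds (genes with a candidate at the promoter, protein-coding genes, GC-matched candidates, sequence length), the dm3 files, the 1482 peaks of higher signal, a consensus of the replicates' strongest candidates, and leaving out each replicate. Leaving out a replicate replaced the IDR list by the pooled candidates found among the strongest of both remaining replicates, since the IDR step could not be rerun.

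The scripts were tested on simulated data. In simulations of 17000 genes, 98.2% of lists of 60 genes with an odds ratio of 4 were called and 2.20% of lists with no change. Other list sizes were not simulated, so these rates do not cover the shorter lists, such as the 8 Hox genes. A planted excess of 15 percentage points for a word came back as 14.9 over 30000 summits, a planted GC difference of -5 as -5.0, and a planted rho of 0.582 as 0.579 over 36000 sites. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.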

Results

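HmgD, a high-mobility-group box protein that binds and bends DNA with little sequence preference, was mapped on chromatin of whole Drosophila melanogaster embryos of mixed sex collected at 0 to 24 h of development. The embryos came from a transgenic line stably expressing HmgD with a green fluorescent protein tag at its C terminus, and chromatin immunoprecipitation used an antibody against the tag. The series held 1 group of 3 biological replicates and no second condition. The comparisons were therefore those between replicates and those between the peaks kept after the irreproducible discovery rate (IDR) step and the other candidates. The candidate lists on the dm6 build held 28193 entries for replicate 1, 30000 for replicate 2, 30000 for replicate 3 and 30000 for the pooled replicates. The IDR list held 2964 peaks, all of them on the arms of chromosomes 2, 3, 4 and X. These 2964 were the entries of highest signal in the pooled list, with a lowest kept signal of 114.7 and a highest signal not kept of 114.6. Kept against not kept was therefore a comparison above and below a single signal level. Read depth is unknown, since the lists hold no read counts.

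The strongest IDR peak, at 2L 480909 to 481270, was nearest to cbt, which encodes a zinc-finger transcription factor, and lay in an intron of ush, a gene outside the naming rule that was looked up afterwards. Its signal, the authors' own value, was 1634, and its summit lay 1406 bp upstream of the nearest annotated transcription start site (TSS). The next strongest were at the promoter of CG14100 (3L 19590454 to 19590779, signal 1399) and in an intron of Lk6, a kinase acting on the translation initiation machinery (3R 11760896 to 11761218, signal 1202). They were followed by peaks at the promoter of the UDP-galactose transporter gene Ugalt (X 2703742 to 2704062, signal 1144) and at the promoter of the wing-vein gene px (2R 22514148 to 22514452, signal 1067). The remaining members of the 10 strongest were nearest to CG11050 (signal 952, intron), Chro, which encodes a chromosomal and spindle protein (943, promoter), and the Polycomb group gene ph-p (885, promoter). CG13323 (875, between genes, 11910 bp from its TSS) and CG1888 (851, promoter) completed the set. These 10 peaks ranked near the top of each replicate's own list, the lowest rank percentile among them being 99.9.

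The question for the replicates was how far they ranked the same sites highly. Over matched candidates, Spearman's rho of the signal was 0.594 between replicates 1 and 2 (11089 matched sites), 0.521 between replicates 1 and 3 (10683) and 0.535 between replicates 2 and 3 (14092). The mean was 0.550 ± 0.0387 (SD, n = 3 pairs). Sites are not independent replicates, and these values describe agreement across sites only. Of the 2964 strongest candidates of each replicate, 1860, 1568 and 1762 were shared by the respective pairs, 58.4% ± 5.01 (SD, n = 3 pairs). Circular shifts of the positions along each arm gave means of 27.6, 25.5 and 25.4 shared sites (permutation test, p = 0.00498 for each pair, the smallest that 200 shifts can give). Of the IDR peaks, 97.9% ± 1.02 (SD, n = 3 replicates) had a candidate summit within 200 bp in a replicate's list, at a median rank percentile of 94.6 ± 0.201. The IDR peaks were drawn from these same replicates pooled, so high values here follow in part by construction. All 3 replicates placed 1287 IDR peaks (43.4%) among their own 2964 strongest, while 42 peaks (1.42%) were in that set for none of the replicates. Summits at an identical position made up 0.518% to 0.860% of the shorter list, so no replicate repeated another.

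IDR peaks lay mostly at promoters. Of 2964 summits, 2106 (71.1%, 95% Wilson interval 69.4 to 72.7) were within 500 bp of an annotated TSS, against 8082 of 27036 candidates not kept (29.9%), an odds ratio of 5.76 (95% interval 5.30 to 6.26). The strongest 2964 candidates of each replicate gave 70.2% ± 2.48 (SD, n = 3), and positions shifted along the arms gave 13.6% ± 0.733 (SD over 1000 shifts; two-sided permutation test, p = 0.002, the smallest that these shifts can give). Coding sequence held 19 IDR summits (0.641%) against 23.2% of the candidates not kept and 13.7% of shifted positions (permutation p = 0.002). Introns held 526 IDR summits (17.7%) and the space between genes 253 (8.54%), both below their shifted shares of 39.5% and 27.2% (permutation p = 0.002 for each). The share in 5' untranslated regions outside the promoter window, 0.810%, did not differ from the shifted share of 0.792% (permutation p = 0.961). The median offset of promoter summits from the TSS was -44 bp (negative is upstream), and 73.9% of them were upstream of it. The control data were not used here, so background at open promoters cannot be separated from binding in this share or in the gene lists and words below. By rank, the promoter share was 72.3% for the 300 strongest pooled candidates, 74.9% for ranks 301 to 1000, 55.3% for ranks 2965 to 6000 and 21.0% for ranks 20001 to 30000.

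**Figure D1:**
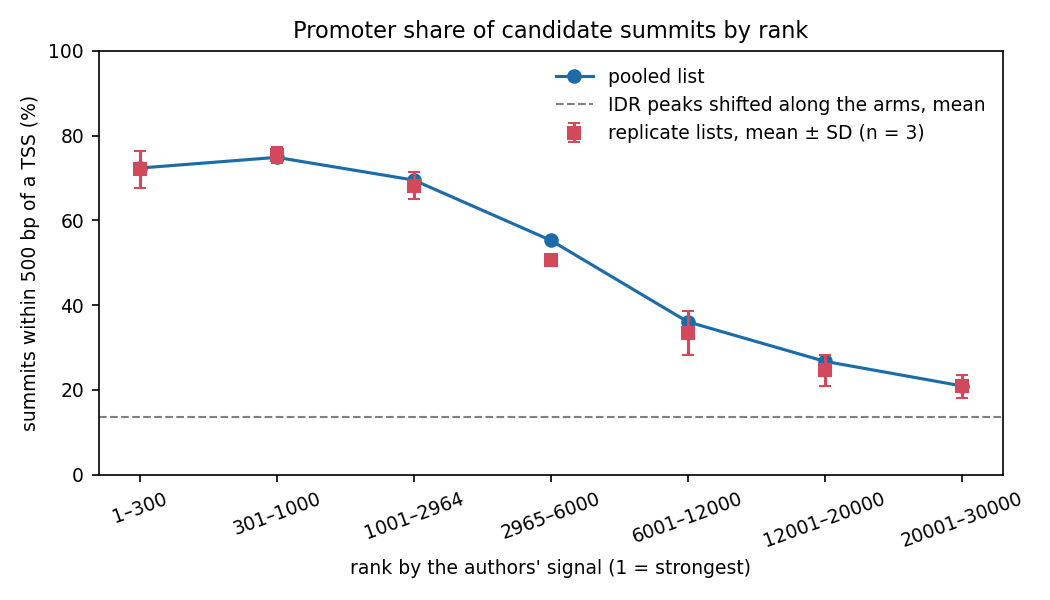
Share of summits within 500 bp of an annotated TSS (vertical axis, percent) by rank of the authors' signal (horizontal axis, rank bins, strongest at left); circles are the pooled list, squares the mean of the 3 replicate lists with bars of 1 SD, and the dashed line the mean of shifted IDR positions. The pooled share lies between 69.5% and 74.9% in the bins down to rank 2964 and at 21.0% in the weakest bin, above the 13.6% of shifted positions.

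Genes for Polycomb and trithorax group proteins, which maintain repressed and active gene states, often had an IDR peak at their promoters. The share was 16 of 22 genes (72.7%; 65.2% ± 18.9 over the replicates' own strongest candidates, SD, n = 3), against 15.4% of all other genes. The named members were ph-p, Sfmbt (2L 13176642 to 13177045, signal 264) and Pc (3L 21317838 to 21318241, signal 233). Cytoplasmic ribosomal protein genes followed with 58 of 93 (62.4%; 60.9% ± 7.16, n = 3), among them RpL7 (2L 10200903 to 10201119, signal 536), RpS27 (3R 25247408 to 25247639, signal 535) and RpL23A (3L 1668629 to 1668854, signal 527). Replication and cell cycle genes had 14 of 26 (53.8%; 47.4% ± 8.01, n = 3), including Dp, the partner of E2F transcription factors (signal 302), the mitotic kinase gene polo (288) and the cyclin gene CycB (222). Genes for chromatin architectural and insulator proteins had 8 of 21 (38.1%; 50.8% ± 2.75, n = 3), led by Chro, the topoisomerase gene Top2 (signal 328) and the insulator cofactor gene Cp190 (212). Mitochondrial ribosomal protein genes had 22 of 73 (30.1%; 30.1% ± 4.94, n = 3), with mRpL41 (signal 777), mRpS23 (765) and mRpS10 (759) highest. In this and every other list, a peak can also lie at the promoter of a neighbouring gene or inside it. The Sfmbt summit lay inside CG43925 and the Dp summit inside Fsn. The Wnt, FGF and EGF ligand genes had 7 of 14 (50%; 33.3% ± 4.12, n = 3), among them wg (signal 192), bnl (187) and spi (179). In Fisher's exact test (two-sided, Benjamini-Hochberg over 28 lists) the adjusted p was 4.03e-08 for the Polycomb and trithorax genes, 3.18e-23 for the cytoplasmic ribosomal proteins and 2.40e-05 for replication and cell cycle. By the same exact test it was 0.0203 for the architectural proteins, 0.00421 for the mitochondrial ribosomal proteins and 0.00627 for the ligands. Leaving out a replicate, which also left smaller sets of 1541 to 1808 peaks, ended the ligand call (21.4%, 21.4% and 7.14% without replicates 1, 2 and 3) and lowered the replication and cell cycle share to 26.9% without replicate 2 and 34.6% without replicate 3, and the mitochondrial share to 19.2% without replicate 1, both still called. The 15.4% of other genes does not apply in these settings, since their share falls with smaller sets. Among genes with a candidate it is higher, and ecdysone response genes at 28.6% lay below other genes there. In the exact test against genes with a candidate peak at their promoter, the architectural (40%, adjusted p = 0.666), mitochondrial (32.8%, 0.923) and ligand (70%, 0.0511) calls were lost, the architectural call also among protein-coding genes (38.1%, 0.0855). With the stronger 1482 peaks the replication and cell cycle (19.2%, exact test, adjusted p = 0.131), mitochondrial (16.4%, 0.0804) and ligand (21.4%, 0.183) lists lost theirs, the ligand list also in the consensus of the replicates (7.14%, adjusted p = 1).

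Histone, chemoreceptor, cuticle protein, tRNA, snoRNA, microRNA, cytochrome P450 and odorant-binding protein genes had lower shares than other genes. Most other genes are protein-coding, at 18.7%, while ncRNA genes as a whole were at 5.09%. The tRNA, snoRNA and microRNA shares were near that ncRNA share, so they do not set these lists apart from ncRNA genes. No IDR peak was within 500 bp of a TSS of 111 replication-dependent histone genes, 119 chemoreceptor genes or 70 cuticle protein genes, nor was any among the strongest candidates of the 3 replicates. The upper 95% Wilson bounds were 3.35%, 3.13% and 5.20%, and the adjusted p was 1.07e-07, 4.03e-08 and 4.84e-05 (Fisher's exact test). Transfer RNA genes had 16 of 295 (5.42%, exact test, adjusted p = 5.28e-07), the strongest at tRNA:Tyr-GTA-1-8 (signal 332) and tRNA:Trp-CCA-2-2 (241). Small nucleolar RNA genes had 14 of 257 (5.45%, exact test, adjusted p = 3.38e-06), led by snoRNA:Psi18S-1275 (293) and snoRNA:Psi28S-2949 (279). MicroRNA genes had 14 of 260 (5.38%, exact test, adjusted p = 2.88e-06), led by mir-9378 (259) and mir-4949 (235). For these RNA genes the TSS was the annotated start of the RNA, and whether transcription starts there was not tested. The mir-9378 summit lay inside CG17124, that of tRNA:Tyr-GTA-1-8 inside CG8036 and p, and that of tRNA:Trp-CCA-2-2 inside CG30122. Cytochrome P450 genes had 2 of 87 (2.30%, exact test, adjusted p = 0.000387), Cyp6u1 (153, summit inside Ufsp1) and Cyp1 (117). Odorant-binding protein genes had 1 of 51 (1.96%, exact test, adjusted p = 0.00674), Obp99b (222). The histone genes lie in a repeated array at 2L 21416953 to 21541681 that held no candidate in any of the dm6 lists. Their 0 was thus fixed before the test, and its bound and p-value say nothing of binding. Histone and transfer RNA genes have near-identical copies to which reads are hard to assign. With the smaller sets that leave out a replicate, the odorant-binding call was lost at an unchanged 1.96%, as with the stronger 1482 peaks and in the consensus, while the tRNA (2.71% to 3.05%), snoRNA (2.33% to 4.28%) and microRNA (1.92% to 4.23%) calls held and the cytochrome P450 call held at 0% without replicates 1 and 2. In the exact test against genes with a candidate at their promoter, the chemoreceptor (still 0%, adjusted p = 0.10), cuticle (still 0%, 0.0740), cytochrome P450 (10%, 0.124) and odorant-binding (10%, 0.423) calls were lost, as was the snoRNA call with a promoter window of 1000 bp (16.7%, 0.694). The histone list, with no candidate at its promoters, could not be tested against genes with a candidate.

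The other 14 lists did not pass the test, with adjusted p from 0.104 to 1 (Fisher's exact test). Segmentation genes had 6 of 24 with a promoter peak, the strongest at the anterior determinant bcd (3R 6759501 to 6759904, signal 264), Hox genes 1 of 8 (Dfd, 139) and dorsoventral patterning genes 3 of 17 (brk, 198). Neural genes had 3 of 25 (elav, 248), muscle and mesoderm genes 6 of 21 (mbc, 342), gut and endoderm genes 3 of 9 (grn, 507), and haemocyte and fat body genes 2 of 17 (apolpp, 154). The elav summit lay inside arg, 300 bp from the elav TSS, and the brk summit inside CG1677 and lncRNA:CR44357. Ecdysone response genes had 4 of 15 (Eip75B, 293), heat shock genes 6 of 21 (Hsp83, 194) and X chromosome dosage compensation genes 4 of 10 (msl-1, 219). Proteasome genes had 12 of 48 (Prosbeta1, 271) and snRNA genes 5 of 32 (snRNA:U1:95Ca, 147). Eggshell and yolk genes had 0 of 18 and E(spl) complex genes 0 of 11. Of all 18164 genes on the arms, 2818 (15.5%; 15.1% ± 1.47, SD, n = 3) had a promoter IDR peak, 18.7% of protein-coding and 5.09% of ncRNA genes. With the smaller sets that leave out a replicate, none of the 14 passed (exact test, adjusted p at least 0.125). Shares were then 8.33% to 16.7% for segmentation, 6.67% to 13.3% for ecdysone response, 4.76% to 19.0% for heat shock, 10% to 20% for dosage compensation, 14.6% to 18.8% for proteasome and 3.12% to 6.25% for snRNA genes. For Hox genes they were 0% to 12.5%, for neural genes 4% to 12%, for muscle and mesoderm genes 19.0% to 23.8%, for gut and endoderm genes 11.1% to 22.2% and for haemocyte and fat body genes 0% to 5.88%. Smaller sets lower the share of other genes too, so these values are not to be read against 15.5%. Ecdysone response genes at 13.3% without replicate 1 or 3 were still above other genes. The dosage compensation list passed with a promoter window of 1000 bp (50%, exact test, adjusted p = 0.0464).

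**Figure D2:**
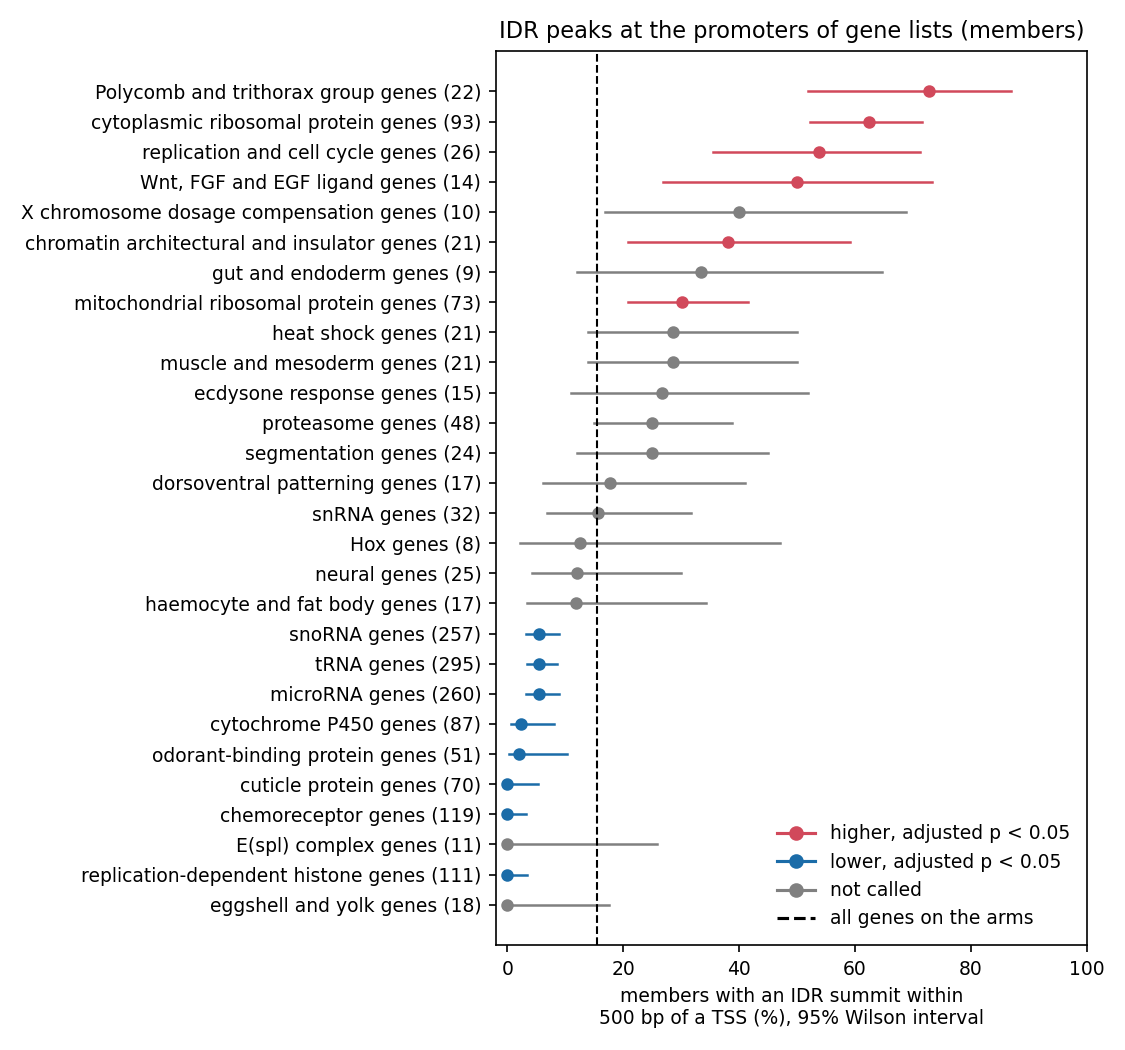
Share of each gene list's members with an IDR summit within 500 bp of a TSS (horizontal axis, percent) with 95% Wilson intervals, for 28 lists with their number of members; red lists had a higher and blue lists a lower share than other genes, grey lists did not pass the test, and the dashed line is the share of all genes. The Polycomb and trithorax list at 72.7% and the cytoplasmic ribosomal proteins at 62.4% lie furthest above the 15.5% of all genes.

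The HmgD gene and its neighbour HmgZ, which encodes a closely related HMG-box protein, both had IDR peaks at their promoters. The HmgD peak (2R 21713187 to 21713590) had a signal of 148, rank 1735, and rank percentiles of 97.6 and 95.2 in replicates 2 and 3, with no matched candidate in replicate 1. The HmgZ peak (2R 21704455 to 21704858) had a signal of 208, rank 730, and a mean rank percentile of 96.6 ± 2.75 (SD, n = 3). Dsp1, another HMG-box gene, had a promoter candidate on X with a signal of 102 that ranked 3713 and was not kept. The 20 kb around HmgD also held an intronic peak of signal 701 at 2R 21703122 to 21703497, which was chosen after its value was seen. In all, the window held 24 pooled candidates, against a median of 9 in windows with a similar number of TSSs.

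**Figure D3:**
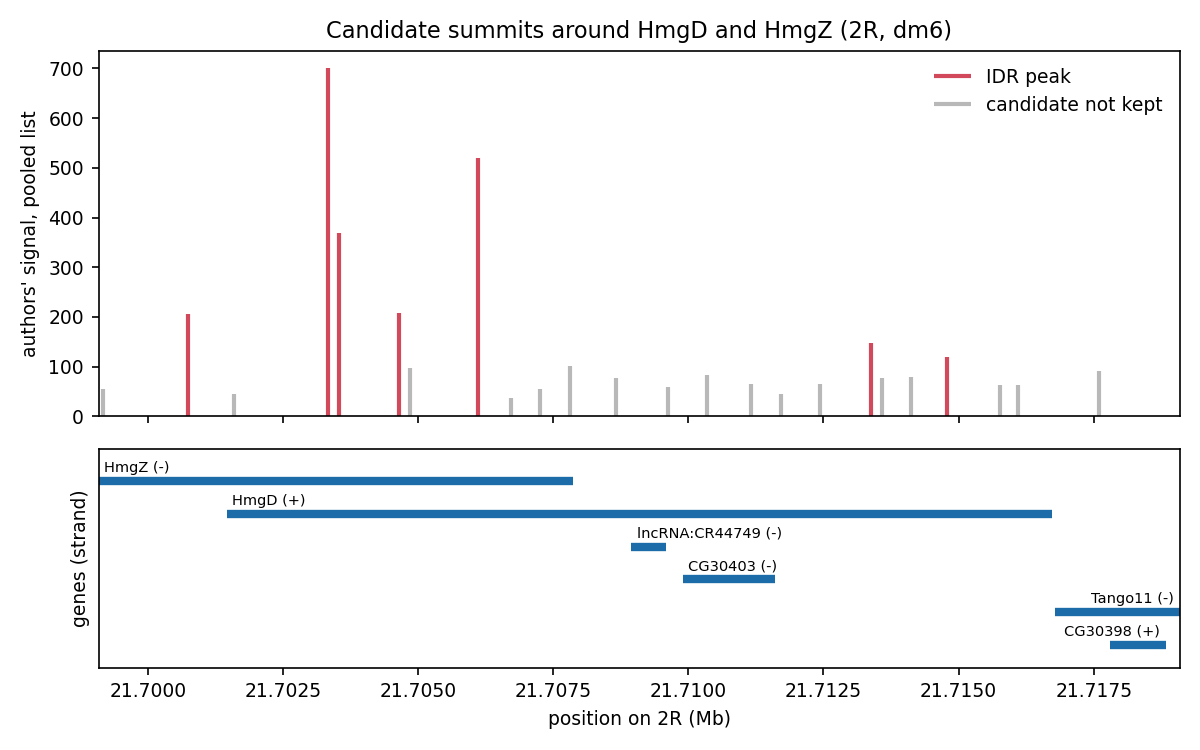
Pooled candidate summits in the 20 kb around HmgD (2R, dm6; horizontal axis, position in Mb) with the authors' signal as bar height (upper panel, red for IDR peaks and grey for candidates not kept) and annotated genes with their strand (lower panel). The window holds 24 candidates, 7 of them IDR peaks, the highest with a signal of 701 inside the overlapping HmgD and HmgZ genes.

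Words of promoter and insulator proteins were more frequent at IDR summits than at the candidates not kept. The DNA replication-related element TATCGATA, bound by the promoter factor Dref, was within 100 bp of 242 of 2964 IDR summits (8.16%) against 1.42% of the candidates not kept. The odds ratio was 6.17 (95% interval 5.23 to 7.28; Fisher's exact test, two-sided, adjusted p = 4.74e-83 over 11 words). The core promoter word GGTCACAC (Motif 1) was at 7.15% against 1.5% (odds ratio 5.07, exact test, adjusted p = 1.88e-62). By the same exact test the CTCF core AGGTGGCGC was at 1.69% against 0.470% (3.64, adjusted p = 9.48e-12), and CGATA, the word of the insulator protein BEAF, at 39.0% against 22.6% (2.19, adjusted p = 1.09e-78). CGATA is part of TATCGATA. The 242 IDR summits with TATCGATA are therefore among the 1156 with CGATA, and the results for these words are not independent. In the strongest candidates of the single replicates these 4 words were at 7.35% ± 1.52, 6.21% ± 0.652, 1.63% ± 0.407 and 38.1% ± 3.55 (SD, n = 3). Their odds ratios were 2.79, 2.35, 2.38 and 1.94 among promoter summits and 3.54, 3.38, 4.22 and 1.87 against candidates matched on GC content, all still called (exact test, adjusted p at most 0.00542). The word TATAAA (odds ratio 1.61, exact test, adjusted p = 8.28e-20) and the A tract AAAAAAA (1.45, adjusted p = 1.43e-11) were also more frequent. Against candidates matched on GC content their odds ratios were 0.972 (exact test, adjusted p = 0.673) and 0.913 (adjusted p = 0.132). The repeat words GAGAG (1.16, exact test, adjusted p = 0.000958), GAGAGAGA (1.71, adjusted p = 6.69e-07) and CACACACA (1.33, adjusted p = 0.000168) passed as well, with shares that differed between replicates. GAGAG was at 23.4%, 30.7% and 34.3% and CACACACA at 4.18%, 8.60% and 9.95% of the strongest candidates of replicates 1, 2 and 3. In replicate 1 these words were less frequent there than in the rest of its list (24.8% and 6.37%). In replicates 2 and 3 they were more frequent than in the rest. All 3 repeat words lost the call among promoter summits, in the consensus of the replicates and without replicate 2, GAGAG and GAGAGAGA also without replicate 3. The GAGAGAGA odds ratios were 1.18 without replicate 2 and 1.16 without replicate 3 (exact test, adjusted p = 0.350 and 0.394). GAGAG also lost its call within 50 bp of the summit (odds ratio 1.08), and with the stronger 1482 peaks GAGAG (1.08, exact test, adjusted p = 0.217) and CACACACA (0.968, adjusted p = 0.826) lost theirs. CACACACA was less frequent without replicate 3 (odds ratio 0.737, exact test, adjusted p = 0.00913). The Zelda word CAGGTA (0.860, exact test, adjusted p = 0.122) and the E-box CAGCTG (1.02, adjusted p = 0.711) did not pass. Against candidates matched on GC content the E-box was more frequent (1.31, exact test, adjusted p = 4.44e-05). The Zelda word was less frequent at the stronger 1482 peaks (0.717, exact test, adjusted p = 0.0237), in the consensus (0.700, 0.0254) and without replicate 1 (0.751, 0.0255) or replicate 3 (0.725, 0.0125). Those sets were not matched on GC content. With all IDR peaks against candidates matched on GC content, the Zelda odds ratio was 0.995 and was not called.

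**Figure D4:**
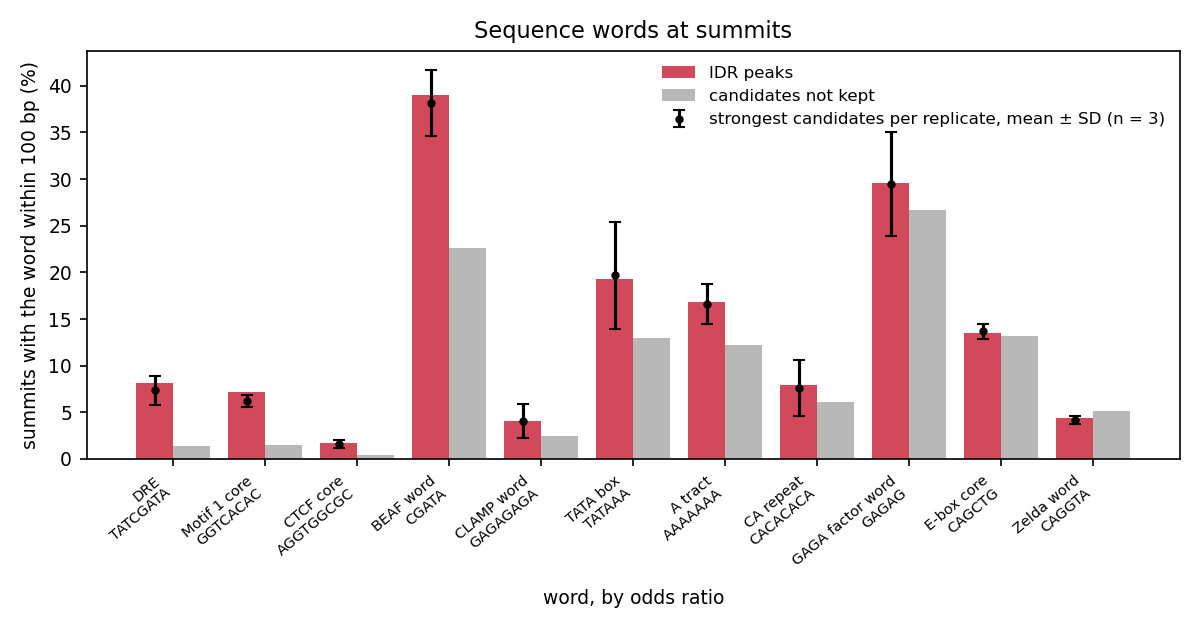
Share of summits with each word within 100 bp on either strand (vertical axis, percent) for IDR peaks (red bars) and candidates not kept (grey bars), ordered by odds ratio; points are the mean of the 3 replicates' strongest candidates with bars of 1 SD. TATCGATA is at 8.16% against 1.42%, while GAGAG at 29.6% against 26.7% lies within the spread between replicates.

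DNA at IDR summits was richer in A and T than at the other candidates, while its GC content was near that of the arms as a whole. Median GC content within 100 bp of the summit was 41.8% (quartiles 37.3 and 47.3) for IDR peaks and 48.3% (41.8 and 54.2) for candidates not kept, and the arms as a whole were at 42.2%. The difference was -6.47 percentage points (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Among promoter summits alone the difference was -3.98 points (permutation p = 1e-05). The strongest candidates of replicates 1, 2 and 3 had medians of 39.3%, 42.3% and 45.3%, each below the rest of its own list, by -5.97, -4.98 and -3.48 points.

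Chromosome 4, the small autosome with much heterochromatin, held 22 IDR peaks against 78 candidates not kept, an odds ratio of 2.58 (95% interval 1.61 to 4.15; Fisher's exact test, adjusted p = 0.00172 over 6 arms). The X chromosome held 522 peaks (odds ratio 1.13, exact test, adjusted p = 0.0329) and arm 3L 555 (0.853, adjusted p = 0.00342). Arms 2L, 2R and 3R did not pass (exact test, adjusted p = 0.434, 0.222 and 0.324). Per Mb of sequence, the 16.3 IDR peaks on chromosome 4 were the fewest, and 3R had 23.4. The chromosome 4 call was lost on leaving out any of the replicates (odds ratios 1.17 to 2.06), with the stronger 1482 peaks (1.68) and in the consensus (1.67). Against sequence length its direction turned. The value there was not an odds ratio but the share of IDR peaks over the share of sequence, 0.737 (binomial test, adjusted p = 0.328). The X call was lost in 4 of the alternatives, among them the dm3 files (exact test, adjusted p = 0.113), and with the stronger 1482 peaks 3L lost its call as well (adjusted p = 0.0586).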

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

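The tests in this part were chosen after the pattern was seen, except the GC comparison among promoter summits, which was planned, and that on intron and intergenic summits. The older dm3 lists held candidates outside the chromosome arms, on sequences that no comparison above used: 183 in replicate 1, 31 in replicate 2, 22 in replicate 3, 30 in the pooled list and 6 in the IDR list. They are given as values from unused sequences, and the counts alone say nothing of binding there. The 6 IDR peaks were on 3RHet (3), 3LHet (2) and U (1), and the 183 entries of replicate 1 had a median rank percentile of 37.6 in their own list.

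The 20 kb around HmgD held 24 pooled candidates, 7 of them IDR peaks. A gene-dense neighbourhood is argued against, since the count lay at percentile 99.98 of 5774 windows with a similar number of TSSs. In replicates 1, 2 and 3 it lay at 99.4, 99.97 and 99.5. Extra copies of the region carried by the tagging construct, which may raise background along the whole stretch, remain a candidate explanation. Candidates more than 500 bp from any TSS numbered 13 against a median of 3, at percentile 99.4 of windows around all genes. These 13 are part of the same 24, and the windows were not matched on TSS number, so they add no separate support. Binding of HmgD at its own locus would give such counts too and was not tested, since the control data were not used here.

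Replicate 1 ranked AT-rich sites higher and repeat words lower than the other replicates. Over 2790 IDR peaks matched in all lists, the Spearman rho of GC content with the rank difference from the other replicates was -0.438 for replicate 1, 0.00111 for replicate 2 and 0.438 for replicate 3; the differences sum to 0 over the replicates, so these values are not independent. GC-dependent recovery of fragments in the libraries, which may act on background as well, remains a candidate explanation: over 4809 matched candidates not kept, outside the peaks that showed the pattern, rho was -0.244, -0.0290 and 0.248 for replicates 1, 2 and 3. For the repeat words, a linear regression on GC content did not account for the whole rank difference. Of the rank difference of the 929 peaks with GAGAG or CACACACA, 49.9% was left after it in replicate 1, 96.7% in replicate 2 and 35.1% in replicate 3 (permutation p = 1e-05, 0.0008 and 0.00038). By the rule set for this test the outcome in replicate 1 was undecided, so no conclusion on GC content alone is drawn. Forms other than the linear one were not tested. The replicates' labels give no biological difference between them, so none was tested.

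IDR summits had a GC content near that of the arms and below that of the candidates not kept. Location at promoters does not account for this difference from the candidates not kept. It was -3.98 percentage points among promoter summits and -7.96 outside them. Coding sequence among the candidates not kept is argued against as the whole cause by -4.98 points over the 779 IDR and 11515 other summits in introns and between genes (permutation p = 1e-05). GC-dependent recovery stays open, given the spread between replicates above, and no biological explanation was tested.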

How the results depend on the processing

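One alternative, the GC comparison outside promoters (-7.96 points), was chosen after seeing the data. The promoter share kept its direction and its side of the threshold in all alternatives run (56.7% to 79.6%), as did the GC difference (-3.98 to -7.96 points) and the words TATCGATA, GGTCACAC, AGGTGGCGC and CGATA. The IDR set shrank by construction to 1482 with the stricter threshold and 1297 in the consensus. Mean rho moved to 0.590 with matching within 100 bp and ranged from 0.521 to 0.594 without single replicates, where the shared top ranged from 52.9% to 62.8%. The share of IDR peaks matched moved to 94.3% within 100 bp, 92.8% with reciprocal overlap and 99.4% with the stricter threshold. Arms called numbered 1 against sequence length, 0 with the stricter threshold and 1 to 2 without single replicates. Gene lists called numbered 6 (3 higher, 3 lower) with genes holding a candidate as background, where fewer genes enter; the higher lists were 3 with the stricter threshold and the lower lists 5 among protein-coding genes, where RNA gene lists drop out. Words called less frequent numbered 1 with the stricter threshold, 1 in the consensus and 0 to 2 without single replicates. Of called values, directions turned for chromosome 4 (0.737, sequence length), the ligand genes (7.14% in the consensus and without replicate 3), GAGAG (0.995 among promoters, 0.974 without replicate 2, 0.954 without replicate 3), TATAAA (0.972) and AAAAAAA (0.913) with GC matching, and CACACACA (0.968 stricter, 0.797 consensus, 0.813 without replicate 2, 0.737 without replicate 3). Leaving out the other replicates did not turn these: the ligand genes were at 21.4% without replicate 1 or 2, with the call lost, and without replicate 1 GAGAG (1.36) and CACACACA (1.37) kept theirs. Beyond what GC matching shows, the cause was not tested. Among values with no call in either setting, directions turned for arm 2L (0.988 in the consensus, 0.991 to 1.02 without single replicates, below 1 without replicates 1 and 2) and arm 2R (1.01, sequence length). They turned for 7 gene lists set against other genes in the same setting: with genes holding a candidate as background, segmentation (27.3%), dorsoventral (21.4%) and ecdysone (28.6%); with the 1000 bp window and among protein-coding genes, dorsoventral (17.6% in each); with the 250 bp window, snRNA (12.5%). With the stricter threshold and in the consensus alike they turned for ecdysone (6.67%), heat shock (4.76%) and snRNA genes (0%). On leaving out replicates they turned for segmentation without 2 and 3 (range over all 3, 8.33% to 16.7%), Hox without 1 (0% to 12.5%), neural without 1 (4% to 12%), ecdysone without 2 (6.67% to 13.3%), heat shock without 1 (4.76% to 19.0%) and snRNA genes in all 3 cases (3.12% to 6.25%). The cause was not tested for these. In all, 37 tested values turned. Of the others, 297 kept their direction and side of the threshold, 37 lost the call and 6 gained it; the 150 mean rank percentiles of named peaks without single replicates carry no test. The cytoplasmic ribosomal list had a higher share than the Polycomb and trithorax list with the stricter threshold (50.5% and 50%), in the consensus (49.5% and 45.5%) and without each single replicate (50.5% to 58.1% and 50% to 54.5%). Depth is unknown, and no paired analysis was possible because there is 1 group.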

Other observations

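The tests of gene families, of words inside and outside promoters and of words of the strongest peaks were chosen after seeing the data; the divergent promoter test was written before its result. Of 59 families of genes sharing a symbol stem (at least 10 members), some of which overlap the lists above, 6 had a higher share of promoters with an IDR peak and 0 a lower one (Fisher's exact test, adjusted p under 0.05). The stems Cyp, Obp, Gr, Or, Ir, Cpr, His, tRNA, snoRNA and mir, among others, were left out. Lists of such genes had lower shares above, so the 0 does not cover them. Translation initiation factors (eIF) had 16 of 44 (36.4%, exact test, adjusted p = 0.0226) and ubiquitin-specific proteases (Usp) 8 of 15 (53.3%, adjusted p = 0.0226). By the same exact test syntaxins (Syx) had 6 of 10 (60%, adjusted p = 0.0325) and proteasome regulatory subunits (Rpn) 7 of 14 (50%, adjusted p = 0.0396). Vacuolar ATPase subunits (Vha) had 9 of 22 (40.9%, exact test, adjusted p = 0.0440) and secretory pathway genes (Sec) 8 of 19 (42.1%, adjusted p = 0.0495). These 6 families were set against all other genes only. They were not tested against protein-coding genes, 18.7% of which had a promoter peak, or against genes holding a candidate. Genes whose symbol is only a database identifier share a stem without being a family, and that stem was left out after its result was seen. The Rpn genes belong to the proteasome list, which as a whole did not pass, and the Prosalpha and Prosbeta stems of that list had 0 of 12 and 2 of 13.

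Within the IDR peaks, TATCGATA was at 11.1% of 2106 promoter summits and 1.05% of the 858 others (odds ratio 11.7, Fisher's exact test, adjusted p = 1.07e-24), and GGTCACAC at 9.73% and 0.816% (13.1, adjusted p = 1.02e-22). The CTCF core AGGTGGCGC went the other way, at 0.997% of promoter summits and 3.38% of the others (0.288, exact test, adjusted p = 4.86e-05), as did GAGAG at 27.1% and 35.8% (0.666, adjusted p = 8.57e-06).

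A hypothesis that HmgD peaks prefer divergent promoter pairs was in line with its test. Of 1906 protein-coding genes with an opposite-strand TSS 400 to 1000 bp upstream, 13.0% had an IDR summit within 200 bp of their TSS, against 7.53% of 7368 genes with none within 2000 bp (odds ratio 1.84, 95% interval 1.57 to 2.15, Fisher's exact test, p = 5.02e-13). Whether expression or promoter type differs between these genes was not tested, and either could account for the odds ratio of 1.84.

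A second hypothesis, that the 300 strongest peaks share a sequence element, found no evidence: of the 10 words of 8 bp most enriched in them against the other IDR peaks on 2L, 2R and X, 0 passed on 3L, 3R and 4 (Fisher's exact test). The lowest unadjusted p there was 0.0501, for GGTTGCCA at 4.41% of 136 strongest peaks and 1.76% of 1192 others. The test asked only whether exact words of 8 bp were more frequent in the strongest peaks than in the other IDR peaks. It does not address shorter words, such as CGATA at 39.0% of all IDR summits, or words common to both sets. With 136 peaks it does not argue against rare words either.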
